A study of Mus musculus with 4 samples.

How the data were processed

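RNA of cecal contents was isolated from each mouse individually, per the labels' protocols, and libraries were made with the TruSeq Stranded total RNA kit. Which mice contributed to each of the 4 libraries is not given in the sources used here. Each deposited table lists the contigs of 1 library with a RefSeq protein identifier and an RPKM value, per the file headers. The contigs were assembled de novo by the authors, once for the 3-week set and once for the 8-week set, per the labels. Both tables of a set hold the same contigs and identifiers in the same order. The assembler, read mapper, protein search, their versions, any removal of ribosomal or host reads, and whether counting used strand are not given in the sources used here. The RPKM values were made by the authors and are rounded to 2 decimals. They correct for contig length and for the total of each library, so a rise of a few abundant contigs lowers the values of all others. Short contigs and multiple contigs of 1 transcript each carry their own value.

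Read counts, library totals and contig lengths were not used here, since the tables hold RPKM only. No counting interval, limit for a value of 0 or count model could therefore be given, and the counting intervals that had been planned were replaced by a rule of size. Within a set, 1 library per group leaves no residual degree of freedom, so no p-value is given there. Added after the data were seen, a fit over both sets used limma with a trend of the spread and Benjamini-Hochberg adjustment on the log2(RPKM + 1) values of shared proteins, with the set as a block and 1 residual degree of freedom. Its spread is that between 2 sets that differ in the start of mannose, pooled over proteins that are not independent. The prior degrees of freedom were estimated as infinite, so proteins of the same level were all given the same spread, and the adjusted p values rest on that. With the labels of the 8-week set exchanged, the residual holds the difference common to both sets, which widens the spread. The prior degrees of freedom of that fit were estimated as 2.95. Both lower the number of calls, so the exchange is no like-for-like check of the main fit. On simulated data with 19646 proteins and independent noise, an adjusted p of 0.05 recovered 32.0% of 200 proteins changed 4-fold and called 2 unchanged ones. It recovered all of 200 changed 16-fold and called 14 unchanged ones. The simulated noise had the same SD of 0.60 for every protein and no correlation between proteins. Real log2 ratios of neighbouring identifiers correlated at 0.68 and 0.47. The simulated numbers of unchanged proteins called therefore do not carry over to the real calls. The planned lists of genes, functions, host markers and taxa could not be matched, because the identifiers come without names and the mouse reference tables hold none of them. The relative depth of 2 libraries was estimated from contigs with 0.5 to 2 RPKM in both, as the depth ratio at which the largest number of contigs had equal read numbers within 0.0075 RPKM. At 3 weeks 1108 of 16362 such contigs met this at the best ratio and a median of 190 at the other ratios tried. At 8 weeks the numbers were 1796 of 23489 and 273. Among contigs of 0.5 to 1 RPKM, 27.1% in the 3-week set and 27.9% in the 8-week set had ratios of whole numbers up to 4 at that depth, against at most 12.2% and 13.1% at displaced depths. At least part of the low values therefore rests on few reads, while most of these contigs had no such ratio.

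HFDM values were divided by a factor before the comparison. It was the mean of the log2 ratios of contigs above 0 in both libraries, after trimming 30% of the ratios and 5% of the mean log2 values at each end, without weights, and came to 0.712 in the 3-week set and 0.910 in the 8-week set. Ratios are on the log2(RPKM + 1) scale, which understates the change of low contigs. Contigs with a mean of at least 1 RPKM in the 2 libraries were kept, and a ratio of at least 2-fold was counted as higher or lower. RPKM values of contigs with the same identifier were summed per protein. Overlaps between sets were set against the number that independent lists of the same sizes would share. The rule for named contigs was fixed before the data were examined. It took, per set, the 2 with the largest and the 2 with the smallest ratio of HFDM over HFD among the 25% of contigs with the highest mean RPKM, which began at 6.92 RPKM in the 3-week set and 5.75 RPKM in the 8-week set. Scaling, minimum, fold threshold, pseudocount and abundant contigs were varied as planned before the data were examined.

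For the closing section, proteins were ordered by the number in their identifier and grouped into blocks of 1000 consecutive numbers. Blocks with at least 100 proteins past the minimum were kept. The median log2 ratio of each block was placed among 10000 random lists of the same size matched on 10 classes of mean RPKM, as a description of these libraries. The functions were tested on simulated data made from the real HFD values, with a noise SD of 0.3 on the log2 scale. For the simulated 3-week comparison with 89188 contigs, 97.5% of 200 contigs changed 4-fold were recovered and 0.626% of unchanged contigs were called. For the simulated 8-week comparison with 117023 contigs, 96.0% were recovered and 0.490% of unchanged contigs were called. The simulated noise was narrower than the real spread. Among real contigs of a protein the SD of the log2 ratio was 0.76 at 3 weeks and 0.78 at 8 weeks. The simulated share of unchanged contigs called therefore does not carry over to the real 2-fold counts. With shuffled ratios the correlation of neighbouring identifiers was 0.0049 in the 3-week set and -0.0032 in the 8-week set. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.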

Results

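Total RNA of the cecal contents of C57BL6/J mice was sequenced to follow what the gut microbes transcribed. All mice were fed a high fat diet (HFD) from weaning, and the supplemented mice also drank water with 2% mannose, a simple sugar (HFDM). The study held 2 sets that differed in when mannose was started. In the 3-week set it was started 3 weeks after weaning and in the 8-week set 8 weeks after weaning, and the mice of both sets were 24 weeks old. Each set held 1 HFD library and 1 HFDM library, so 4 libraries were compared and no group had a replicate. The contigs of a set came from an assembly of that set, so a contig was compared only within its set. The 3-week assembly listed 114502 contigs and the 8-week assembly 153974. Contigs were paired with RefSeq protein identifiers, without product, gene or organism names, so the features are described here by identifier and as groups. The counts of genes, pathways and taxa that were planned could therefore not be made.

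Transcript abundance was given as RPKM, which is read number divided by contig length and by the total of the library. The number of reads per library is unknown. Its ratio within a set was read from the steps of low values, since contigs with equal read numbers in both libraries have the same RPKM ratio. The HFDM library of the 3-week set had 0.991 times the depth of its HFD library, and in the 8-week set the ratio was 1.035. The libraries of a set were therefore of closely similar depth. Contigs listed at 0 were few, with 539 in the 3-week HFD library, 1291 in the 3-week HFDM library, 1241 in the 8-week HFD library and 1362 in the 8-week HFDM library. With 1 library per group, each difference within a set compares 2 libraries and has no replicate check.

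The summed RPKM was concentrated in few contigs, and in both sets more so in the mannose library. In the 3-week set the 10 most abundant contigs held 20.5% of the summed RPKM in HFD and 22.3% in HFDM. At 8 weeks they held 8.61% in HFD and 13.1% in HFDM. At 3 weeks 321 contigs carried 50% of the summed RPKM in HFD and 134 did so in HFDM. The corresponding numbers of the 8-week set were 1237 contigs in HFD and 902 in HFDM. Much of this abundance lay in contigs without a protein match, which made up 19.4% of the contigs of the 3-week assembly and 19.9% of those of the 8-week assembly. They held 43.0% of the summed RPKM in the 3-week HFD library and 45.3% in the 3-week HFDM library. At 8 weeks they held 30.9% in HFD and 32.1% in HFDM. Of the 100 most abundant contigs, 59 had no match in 3-week HFD and 52 in 3-week HFDM. In 8-week HFD the number was 57 and in 8-week HFDM 49. Any removal of ribosomal reads is not given, so whether unmatched contigs hold ribosomal RNA is unknown. A difference in such removal between libraries cannot be told apart from a difference in transcripts. The most abundant contig of the 8-week set, which had no protein match, stood at 45550 RPKM in HFD and 109341 RPKM in HFDM. It alone held 2.36% of the summed RPKM in HFD and 6.32% in HFDM, and so made most of the 8-week difference in the top 10. The 8-week values were not recomputed without this contig. The fifth most abundant contig of the 3-week set, also unmatched, stood at 6369 RPKM in HFD and 50792 RPKM in HFDM. Other abundant contigs were lower in HFDM. The third most abundant contig of the 3-week set stood at 93999.7 RPKM in HFD and 21578 RPKM in HFDM, while contigs 2044 and 1193 of the 8-week set stood at 17605 and 14357 RPKM in HFD and at 11634 and 9837 RPKM in HFDM. Among contigs with a protein match alone, a choice made after seeing the data, the 8-week libraries differed less, and the 10 most abundant held 6.69% in HFD and 7.51% in HFDM.

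**Figure D1:**
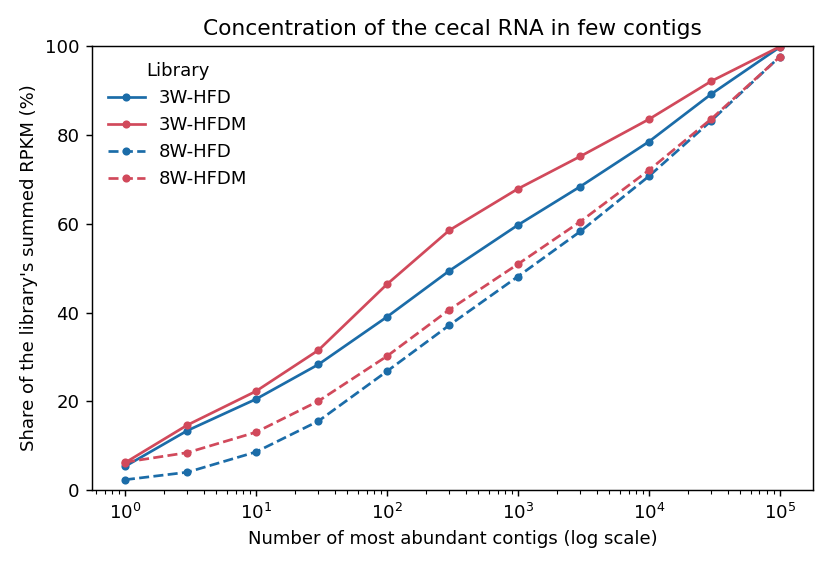
Share of each library's summed RPKM, in percent, held by its most abundant contigs, whose number is on a logarithmic axis. Solid lines are the 3-week set, dashed lines the 8-week set, blue HFD and red HFDM, with 1 library per line. The 100 most abundant contigs held 39.0% in 3-week HFD, 46.3% in 3-week HFDM, 26.8% in 8-week HFD and 30.2% in 8-week HFDM.

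The first comparison asked which cecal transcripts differed when mannose was started 3 weeks after weaning. Among 91298 contigs with a mean of at least 1 RPKM, 13440 were at least 2-fold higher in HFDM and 11868 at least 2-fold lower, after the libraries were scaled to each other. The remaining 65990 contigs lay within 2-fold. Among abundant contigs the largest ratio of HFDM over HFD was that of contig 114412, which had no protein match and stood at 0.12 RPKM in HFD and 1330 RPKM in HFDM. Contig 3929, also unmatched, stood at 1.01 RPKM in HFD and 578 RPKM in HFDM. On the log2(RPKM + 1) scale the smallest ratios were those of contig 109176, matched to the protein WP_042399965, with 438 RPKM in HFD and 0.06 RPKM in HFDM, and of the unmatched contig 35179, with 577 and 0.31 RPKM. With a pseudocount of 5 the smallest were instead those of contigs 46229 and 107658, and as deposited those of contigs 46229 and 35179. The SD of the log2 ratios over contigs was 1.07.

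Contigs with and without a protein match were distributed differently in the 3-week set. Of 73416 contigs with a match, 11550 were at least 2-fold higher in HFDM and 8878 at least 2-fold lower. Of 17882 contigs without a match, 1890 were at least 2-fold higher and 2990 at least 2-fold lower. The median log2 ratio was 0.03 with a match and -0.15 without one. The balance of higher and lower contigs also varied with abundance. Among the 207 contigs with a mean of 1000 RPKM or more, 88 were at least 2-fold higher in HFDM and 20 at least 2-fold lower, with a median log2 ratio of 0.82, or 0.32 with the values as deposited. Among 50902 contigs of 1 to 5 RPKM, 5488 were at least 2-fold higher and 5438 at least 2-fold lower, with a median of -0.03. These numbers depended on the scaling. With the RPKM values as deposited, 7428 of the 3-week contigs were at least 2-fold higher and 21495 at least 2-fold lower, so that 25.7% of the contigs past the threshold were higher, against 53.1% after scaling. Under upper-quartile scaling 12033 were higher and 13376 lower. The scaling moved the median log2 ratio of contigs by 0.37, from -0.38 to -0.01.

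The second comparison asked the same of the set in which mannose was started 8 weeks after weaning. Among 124131 contigs with a mean of at least 1 RPKM, 9578 were at least 2-fold higher in HFDM and 12276 at least 2-fold lower, while 102277 lay within 2-fold. The SD of the log2 ratios was 0.87, against 1.07 in the 3-week set, and 82.4% of the contigs lay within 2-fold, against 72.3% in the 3-week set. On the log2(RPKM + 1) scale the largest ratio was that of contig 1207, which was listed at 0 in HFD and stood at 212 RPKM in HFDM. Contig 178, which ranked first with a pseudocount of 5, stood at 1.10 RPKM in HFD and 444 RPKM in HFDM. The smallest ratios were those of contig 54978, with 567 RPKM in HFD and 0.40 RPKM in HFDM, and of contig 124657, with 593 and 0.68 RPKM, although contig 130774 ranked lowest with a pseudocount of 5 and contig 68057 with 0.5. Contigs 1207, 178, 54978 and 124657 had no protein match. Of 100008 contigs with a match, 8221 were at least 2-fold higher in HFDM and 10258 at least 2-fold lower, and of 24123 contigs without a match, 1357 were higher and 2018 lower. Among the 183 contigs with a mean of 1000 RPKM or more, 28 were at least 2-fold higher and 32 at least 2-fold lower, with a median log2 ratio of -0.05. With the values as deposited, 7517 contigs were at least 2-fold higher and 14370 at least 2-fold lower, and under upper-quartile scaling 11599 were higher and 10970 lower.

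**Figure D2:**
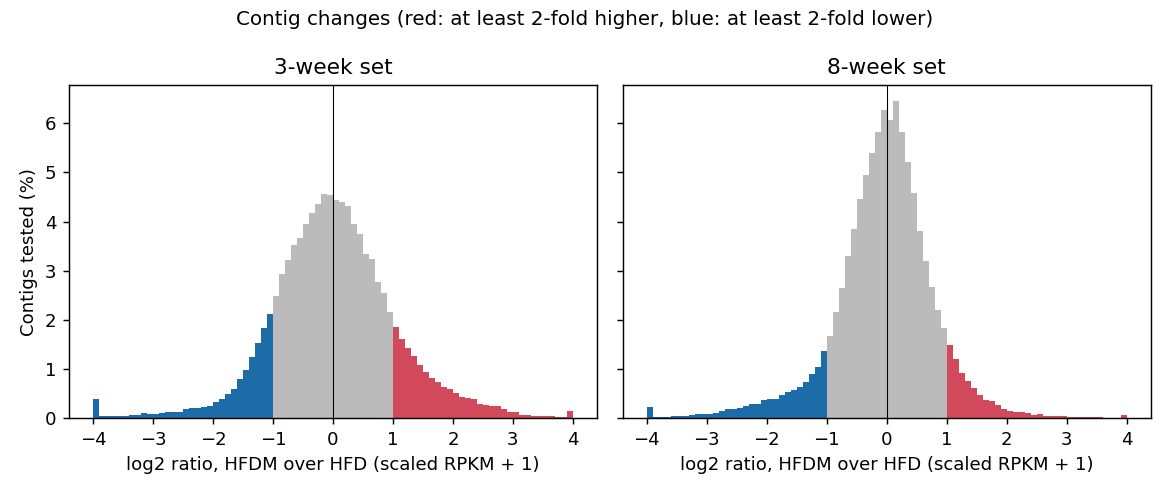
Distribution of the log2 ratio of HFDM over HFD (scaled RPKM plus 1) over the contigs tested in each set, as the percentage of contigs per bin of 0.1. Contigs at least 2-fold higher in HFDM are red and those at least 2-fold lower are blue, and the outermost bins at -4 and 4 collect all larger ratios. The 3-week distribution, with an SD of 1.07, is wider than the 8-week distribution, with an SD of 0.87.

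Contigs matched to the same protein gave a measure of spread within the libraries, which is not an error between mice. At 3 weeks 12386 proteins had 2 or more contigs past the minimum, and the SD of the log2 ratio among contigs of a protein was 0.76, against 1.08 over all these contigs. For the 8-week set the SD among contigs of a protein was 0.78 over 17784 proteins, against 0.92 over all these contigs. All contigs of a protein lay on the same side of 0 for 61.8% of these proteins in the 3-week set and for 53.0% in the 8-week set. When the RPKM values were summed per protein, 7712 of 51154 proteins were at least 2-fold higher in the 3-week HFDM library and 5637 at least 2-fold lower. At 8 weeks 5245 of 64162 proteins were at least 2-fold higher and 5309 at least 2-fold lower.

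The third comparison asked whether the early and the late start of mannose went with differences in the same proteins. The assemblies shared 23326 protein identifiers, of which 19646 had a summed RPKM with a mean of at least 1 in both sets. Of these, 960 proteins were at least 2-fold higher in HFDM in both sets, where independent lists of these sizes would share 354. Another 427 proteins were at least 2-fold lower in both sets, against 168 for independent lists. Fewer proteins than in independent lists went opposite ways, with 231 higher at 3 weeks and lower at 8 weeks, against 351, and 85 lower at 3 weeks and higher at 8 weeks, against 169. Across proteins, which are not independent replicates, the log2 ratios of the 2 sets correlated with a Pearson r of 0.29 and a Spearman rho of 0.19. The correlation was larger among abundant proteins. It was 0.50 over the 3074 proteins with a mean of at least 20 RPKM in both sets and 0.58 over the 488 proteins with at least 100 RPKM. The log2 ratios of the 2 sets had the same sign for only 52.3% of the 19646 proteins. The share was 58.4% of the 3074 and 67.8% of the 488. The sets shared no library. In a fit chosen after seeing the data, with the set as a block and 1 residual degree of freedom, limma called 482 of the 19646 proteins higher in HFDM and 356 lower at an adjusted p of 0.05, with the 3-week and 8-week starts treated as repeats of 1 contrast. With the values as deposited it called 104 higher and 376 lower. With the labels of the 8-week set exchanged, the only other split within the sets, it called 0 proteins, and 215 were higher and 106 lower at an unadjusted p of 0.05, against 1871 and 813 with the true labels. The exchange moves the difference common to both sets into the residual, so fewer calls were built in. These numbers therefore decide nothing about the 482 and 356 calls. Of the 482 higher proteins 233 lay between WP_016318000 and WP_016320999, and of the 356 lower ones 128 lay between WP_042393000 and WP_042402999. These stretches of identifiers held 902 and 146 of the 19646 proteins. They were chosen after their values were seen, so the counts within them are no separate evidence. Since the proteins are not independent replicates, neither are the calls.

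Named after their values were seen, and ranked by whichever set's log2 ratio lay nearer 0, the 2 proteins with the largest ratios in both sets were WP_004896951 and WP_004064712. WP_004896951 stood at 0.98 RPKM in HFD and 122 RPKM in HFDM at 3 weeks, and at 1.02 and 207 RPKM at 8 weeks, with 1 contig in each assembly. WP_004064712 stood at 9.71 and 44.6 RPKM at 3 weeks over 3 contigs, and at 46.1 and 240 RPKM at 8 weeks over 28 contigs. By the same rule the smallest ratios were those of WP_008826257 and WP_005946674. WP_008826257 stood at 261 RPKM in HFD and 1.30 RPKM in HFDM at 3 weeks, and at 51.8 and 1.70 RPKM at 8 weeks. WP_005946674 stood at 121 and 4.34 RPKM at 3 weeks, and at 466 and 1.59 RPKM at 8 weeks. These 4 were taken among proteins with a mean of at least 20 RPKM in both sets. Ranked by the mean of the 2 log2 ratios, WP_004896951 stayed first with 6.63, but WP_012420022 came second with 3.29, from 5.30 at 3 weeks and 1.29 at 8 weeks. By that mean WP_005946674 was lowest with -5.76, followed by WP_042399965 with -5.61 and WP_008826257 with -5.37.

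**Figure D3:**
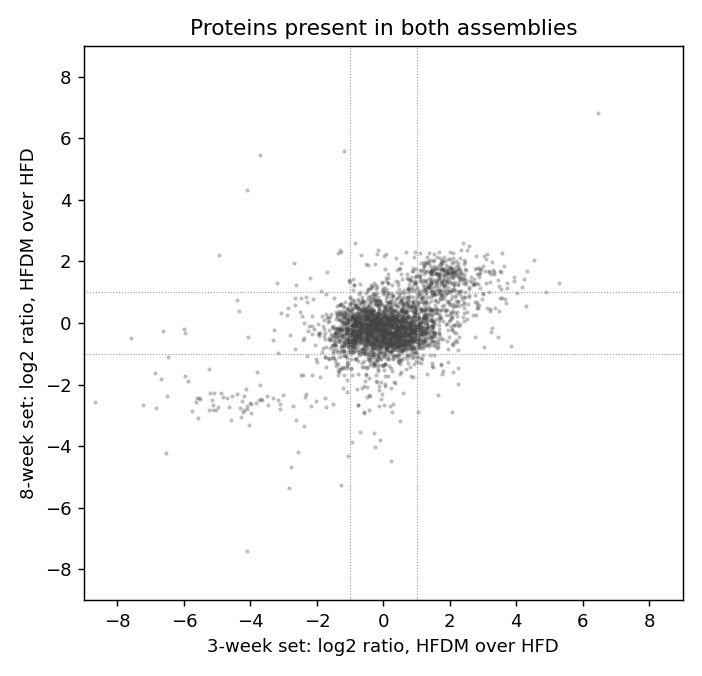
Log2 ratio of HFDM over HFD in the 3-week set (x axis) and in the 8-week set (y axis) for the 3074 proteins with a mean of at least 20 RPKM in both sets, 1 point per protein, with dotted lines at 2-fold. In the upper right corner 308 proteins were at least 2-fold higher in both sets, and in the lower left corner 116 were at least 2-fold lower in both.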

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

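The values in this part are those in which the 3-week and the 8-week set went opposite ways. With 1 library per group these differences between sets were not tested. In 3 of 5 classes of abundance, contigs without a protein match had a lower median log2 ratio than matched contigs in the 3-week set and a higher one in the 8-week set. A pair of these classes is flagged, since the difference was at least 0.1 on the log2 scale in both sets. The difference between unmatched and matched contigs of 5 to 20 RPKM was -0.24 at 3 weeks and 0.13 at 8 weeks. For contigs of 20 to 100 RPKM it was -0.13 at 3 weeks and 0.19 at 8 weeks. From 1 to 5 RPKM it was -0.16 at 3 weeks and, below that limit, 0.06 at 8 weeks. In the remaining classes the sets had the same sign, with 0.40 and 0.07 from 100 to 1000 RPKM and -0.19 and -0.78 from 1000 RPKM. Among proteins present in both assemblies, 231 were at least 2-fold higher in HFDM at 3 weeks and at least 2-fold lower at 8 weeks, and 85 went the other way. Both numbers were below those of independent lists.

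Of 50 blocks of consecutive protein identifiers present in both sets, 30 had medians of opposite sign after scaling and 19 with the values as deposited. The 5 flagged here are those whose medians also lay outside the central 99% of matched random lists in both sets. In the block starting at WP_016322000 the median log2 ratio was 1.05 at 3 weeks and -0.34 at 8 weeks. In the blocks starting at WP_023346000 and WP_023347000 it was 0.85 and 0.92 at 3 weeks, and -0.47 and -0.45 at 8 weeks. In the blocks starting at WP_008862000 and WP_025278000 it was -0.58 and -0.46 at 3 weeks, and 0.26 and 0.27 at 8 weeks. These 10 medians kept their sign with the values as deposited.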

How the results depend on the processing

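Contig counts at 3 weeks are given as higher then lower, against 13440 and 11868, and at 8 weeks against 9578 and 12276. With the values as deposited the 3-week counts were 7428 and 21495, because that scaling moves the median of all contigs. With a minimum of 5 RPKM they were 7952 and 6430 at 3 weeks and 4330 and 5901 at 8 weeks. A 4-fold threshold left 3414 and 2414 at 3 weeks and 1340 and 3479 at 8 weeks, and a 1.5-fold threshold gave 23698 and 23466, and 22494 and 25126. With a pseudocount of 5 the counts were 6496 and 4228, and 2813 and 4706. Counts stayed within 1.5 times under median-ratio and upper-quartile scaling, no minimum, contigs above 0 in both libraries, a pseudocount of 0.5, removal of the 100 most abundant contigs and matched contigs only, although under upper-quartile scaling the larger count changed sides in both sets, with 12033 higher and 13376 lower at 3 weeks and 11599 higher and 10970 lower at 8 weeks. Among matched contigs alone, a choice made after seeing the data, as were the other choices about matched contigs, single-contig proteins and blocks, the top 10 contigs held 9.40% in 3-week HFD, 11.2% in 3-week HFDM, 6.69% in 8-week HFD and 7.51% in 8-week HFDM, and 1627, 661, 2800 and 2346 contigs held 50% in 3-week HFD, 3-week HFDM, 8-week HFD and 8-week HFDM. The correlation between sets was 0.19 by Spearman and 0.11 after subtracting block medians. With 1 contig per protein in each assembly 331 proteins were higher and 185 lower in both sets, against 143 and 77.9 for independent lists, and without the 7 blocks that stood above the random lists in both sets 540 were higher in both, against 207. Of the proteins limma called with the set as a block, also chosen after seeing the data, 104 were higher as deposited, against 482. With a minimum of 5 RPKM 229 of 10168 proteins were lower, against 356 of 19646. Of 168 recomputed values, 123 stayed within 1.5 times, 45 moved further and 0 reversed. Counts and shares have no sign to reverse, so only the log2 ratios of named contigs and the correlations could have done so. Minimum contig length, thinning to equal reads and the functional lists were not run, as the tables hold no lengths, counts or names. Leaving out a library leaves no residual degree of freedom. The unknown read numbers limit the low contigs most.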

Other observations

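Of the tests in this part, those on mean expression and on abundant and scarce proteins of blocks were set up before their results were seen, and the others after. A pair of protein groups with consecutive identifiers each went the same way in both sets. The 1147 proteins numbered from WP_016318000 to WP_016320999 that passed the minimum in the 3-week set had a median log2 ratio of 1.95, and 98.2% of them were higher in HFDM. Their share of the summed RPKM was 2.01% in HFD and 6.89% in HFDM. At 8 weeks 1108 proteins of this stretch had a median of 0.89, 88.0% were higher in HFDM, and the share was 1.67% in HFD and 4.25% in HFDM. The blocks of the stretch differed at 8 weeks. The block starting at WP_016320000 had a median of 0.31 with 63.7% higher. Those starting at WP_016318000 and WP_016319000 had medians of 0.995 and 0.963 with 95.2% and 96.9% higher. The proteins from WP_042393000 to WP_042402999 went the other way. At 3 weeks 177 of them had a median of -3.10 and 95.5% were lower in HFDM, with summed values of 5916 RPKM in HFD and 317 RPKM in HFDM. At 8 weeks 501 of them had a median of -1.65 and 97.8% were lower, with 11995 RPKM in HFD and 2286 RPKM in HFDM. All 4 medians kept their sign with the values as deposited, at 1.49, 0.77, -3.35 and -1.76. Both stretches were chosen after their values were seen.

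The overlap between the sets was unevenly spread over these stretches. Of 308 proteins with at least 20 RPKM that were at least 2-fold higher in both sets, 184 lay in the first stretch, which held 266 of the 3074 proteins compared. The second stretch held 39 of them, and 39 were at least 2-fold lower in both sets. Since the stretches were chosen after their values were seen, these counts are no separate evidence. Across 13592 shared proteins in blocks of at least 10, the correlation between sets was 0.34, and 0.11 after the block medians were subtracted.

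Among other blocks, at 3 weeks the 4 blocks from WP_016290000 to WP_016293999 had medians of -0.63, -0.47, -0.60 and -0.75, all below every random list, and the block starting at WP_016292000 stood at 74353 RPKM in HFD and 24568 RPKM in HFDM. At 8 weeks the same 4 blocks had medians of -0.19, -0.04, -0.10 and -0.08, which lay within the central 99% of random lists. Their summed RPKM was still lower in HFDM at 8 weeks, at 0.68, 0.80, 0.67 and 0.86 times HFD after scaling. At 3 weeks these scaled ratios of sums were 0.48, 0.64, 0.46 and 0.59. The difference between the sets was not tested. The blocks starting at WP_012419000 and WP_012420000 had medians of 0.98 and 0.94 in the 8-week set, with 98.7% of the proteins of each higher in HFDM. These medians lay above the 0.89 of the first stretch at 8 weeks, as did the 1.14 of the block starting at WP_019892000.

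In both sets proteins with neighbouring identifier numbers changed together. The correlation of the log2 ratios of neighbours was 0.68 at 3 weeks and 0.47 at 8 weeks when their numbers differed by 1, and fell to 0.04 and 0.02 for distances above 1000 and up to 10000. Blocks of 1000 numbers with at least 100 proteins covered 11472 of 51154 proteins at 3 weeks and 17928 of 64162 at 8 weeks. The blocks held 51.2% of the variance of these proteins' log2 ratios at 3 weeks over 64 blocks and 31.3% at 8 weeks over 87. The correlation of neighbours at distances of 11 to 100 was still 0.21 in the set where it was lower. Whether neighbouring genes on one transcript account for the shared changes cannot be told from it. These distances are between identifier numbers, and nothing here links the numbers to gene positions. Mean expression alone does not account for the shared changes, because at least 53.1% of the blocks in each set lay outside the central 99% of random lists matched on it. A candidate explanation is that neighbouring numbers come from the same source organism and that the RNA of whole organisms differed between the libraries. It cannot be told apart from other reasons for neighbours to move together. The medians of the more and of the less abundant proteins correlated over blocks with r = 0.94 or more in both sets, but in 100 random splits of the blocks the correlation was 0.96 or more, so this test decides nothing. The files name no organism, and RNA alone cannot separate more cells from more RNA per cell. Whether mannose underlies the differences cannot be told apart from any other difference between 2 libraries, with 1 library per group. Block medians correlated between the sets with r = 0.43 (Spearman rho 0.12) over 50 blocks. Of these blocks 30 had medians of opposite sign after scaling and 19 with the values as deposited. The limma fit over both sets called 482 proteins higher and 356 lower, or 104 and 376 with the values as deposited. Of the 482 higher proteins 233 lay in the first stretch, which was chosen after its values were seen.

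As deposited, the typical contig was lower in the 3-week HFDM library, with a median log2 ratio of -0.38. A larger share of the 100 most abundant contigs may explain part of this, since the median of the other contigs at equal sums was -0.20, but it did not reach 0. Few reads behind low contigs are not the whole cause, since contigs of 20 to 100 RPKM had a median of -0.48. Division by unequal library totals does not account for it either, since the totals used for RPKM, estimated from contigs with equal read numbers, differed by -0.013 on the log2 scale. Whether those totals count reads outside the listed contigs is not given, so a different share of such reads stays open. A biological difference in composition stays open as well.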
